A study of Homo sapiens with 18 samples.

How the data were processed

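Gene expression was measured on 18 Illumina HumanHT-12 V4 bead arrays, 3 for each of 6 groups. The cells were T47D-Y, a variant of the human breast cancer line T47D that lacks the progesterone receptor (PR) and is called PR-null here, and 2 stable clones of it, 1 carrying an expression plasmid for the PR-A isoform and 1 for the PR-B isoform. Per the labels' protocols, cells were kept for 1 day in medium with steroid-depleted serum and then given ethanol vehicle or R5020 (promegestone, a synthetic progestin) for 24 h. The R5020 concentration is written in the labels as 10e-8 M, which can be read in more than 1 way and is repeated here as written. Per the labels, total RNA was isolated with Trizol, cleaned on RNeasy columns with DNase I and amplified to biotinylated cRNA. The labels number the replicates 1 to 3 within each group but do not say that they came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. With 1 clone per isoform, a difference between isoforms and a difference between clones cannot be told apart in any comparison of the lines.

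The deposited table gives, per the file headers, a mean bead intensity on a linear scale for 47323 probes on each array, not normalized between arrays. It also gives a detection p-value per probe and array, which the deposited values show to be a share out of 770 negative control steps. The number of beads behind each intensity was deposited as well and was used only to describe the arrays. The table holds 72 per-sample columns, of which the 18 columns of bead standard errors were not used. A second deposited table holds the authors' processed values, which are log2 intensities that, judged from the values themselves, the authors had quantile normalized without background correction. The sorted columns differed by at most 0.00822 and lay within 0.00127 of the log2 of the quantile means of the signal, with column medians of 6.73 on all 18 arrays. Each column had a Spearman correlation of 1.00 with the signal of its own array. Scale, direction and the absence of centring follow from that match, and any step that leaves ranks and quantile means alone stays unknown. The scanner software and its settings were not given in the sources used here, and the files give no slide or scan date, so no test by slide was made.

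On each array between 18526 and 21362 probes, 39.2% to 45.2%, had a detection p-value under 0.05, the median signal was between 95.5 and 113 intensity units, and the median number of beads per probe was between 18 and 22. Of 92 external RNA control probes at most 2 were detected on any array. Pearson correlations of normalized values were 0.983 to 0.992 for the 18 pairs of arrays within a group and 0.944 to 0.991 for the 135 pairs between groups. The number of arrays limits the precision.

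Intensities were background corrected and normalized with neqc of limma 3.58.1 in R 4.3.3 (normal-exponential correction with the background inferred from the detection p-values, offset 16, quantile normalization, log2), with files read through the package data.table (version 1.17.8). The 24523 probes with detection p under 0.05 on at least 3 arrays were kept, and each gene was represented by its probe with the highest mean over all arrays, which left 18875 genes. Gene names came from the platform's annotation, updated through current human gene tables (GRCh38.p14, used for names only): 35672 probes were named through an Entrez identifier, 85 through a RefSeq accession and 11474 kept the file's own name, as did 3882 of the tested genes. The files name no genome build, so no coordinates are given. Of 4258 genes with more than 1 probe past the filter, no named gene with a called change had another probe called in the opposite direction (0 of 295 pairs of another probe and a contrast, in which a probe can recur). In 98 of these pairs the other probe was not called, in 18 of them with the opposite sign. Chromosomes are given as in the annotation.

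One limma model with a term for each group was fitted to all 18 arrays, with no block (12 residual degrees of freedom and 5.51 prior degrees of freedom), and 9 contrasts were taken from it: R5020 against vehicle in each line, the 3 differences between these responses, and the 3 differences between the lines with vehicle. A gene is said to have changed when its Benjamini-Hochberg adjusted p within the contrast was under 0.05, with no threshold on the fold. These choices, the groups, the lists and the alternatives in the closing section were fixed before the data were examined, except where said. All adjusted p-values are from limma, with n = 3 arrays per group, and errors are SD between arrays for group means and SE for log2 fold changes. Where a gene was detected on no array of the dimmer group, the fold is a bound ("at least"): the brighter group's mean against, per array, the higher of the lowest detected signal and the gene's own value.

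Gene lists were tested with limma's camera (preset inter-gene correlation 0.01, adjusted over lists), and again with the correlation estimated from the data. Of the 19 lists tested 1 is not reported here, and the other 18 were progestin-induced genes, FOXO target genes, senescence and secretory phenotype genes, DNA replication genes, mitosis genes, estrogen-response genes, luminal markers, basal markers, fibroblast markers, leukocyte and endothelial markers, fatty acid synthesis genes, cholesterol synthesis genes, interferon-stimulated genes, NF-kB and inflammatory genes, hypoxia and glycolysis genes, unfolded protein and stress response genes, steroid receptors and coregulators, and cell adhesion genes. Some share members, such as the 4 genes common to the senescence and the NF-kB lists and the 2 common to the progestin and the FOXO lists. Counts of list members are given over all genes tested and, beside them, adjusted over the list alone.

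The genes named are PGR, and for each contrast the genes with the largest changes up and down among those that passed the test and, for contrasts of 2 groups, whose arrays did not overlap (10 each way, or 5 each way for the PR-null response and the comparisons with it). Symbols of uncharacterised loci were passed over. From each list up to 4 members with the largest moderated statistic are named besides. FOXO1, named in the title of the series, fell outside this rule, and it and further values of CDKN1A and of the interferon genes IFNB1, IFNL1 and IFNL2 are given outside it, chosen after their values were seen. PTPRC, CD3D, CD3E, LYZ and NR3C1 were likewise named after their values were seen.

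Because the labels use the same numbers 1 to 3 in every group, the correlation of deviations from the group means was computed for each pair of groups. Same-numbered vehicle arrays of different lines correlated at 0.182 to 0.561 for all 3 numbers in every pair of lines, above the limit of 0.1 set for pairing, so the numbers pair the vehicle arrays; the pairing comes from the values, not from the labels. Within each line, vehicle and R5020 arrays of the same number correlated between -0.161 and 0.00910, so they are not paired.

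For contrasts that share control arrays, 20 simulations of unchanged groups gave the correlation and covariance expected with no effect. The fit and the list test were tested on simulated data before use: for R5020 against vehicle in the PR-B line, with 18875 genes and 50 changed genes per size, 22% of changes of 0.5 log2 units were recovered, 78% of changes of 1 and 100% of changes of 2 or 3, and 7 unchanged genes were called. A simulated list of 30 genes shifted by 0.3 had an adjusted p of 7.19e-12 and an unshifted list 0.327. Simulated genes varied independently of each other, so these values cannot test the preset inter-gene correlation of 0.01. The alternatives tried were no background correction, scaling to a common median, the authors' processed values, no filter and a stricter filter, every probe tested, only the arrays of the contrast, trend and robust variance, stricter thresholds, a replicate block, the estimated correlation, and leaving out each array in turn.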

Results

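To compare the transcriptional responses of the 2 progesterone receptor isoforms, expression was profiled in PR-null T47D-Y breast cancer cells and in the PR-A and PR-B clones made from them, each after 24 h with vehicle or R5020. Each of the 6 groups held 3 arrays, and 18875 genes were tested. PGR, the gene of the progesterone receptor on chromosome 11 (probe ILMN_1811014), was not detected on any of the 6 PR-null arrays (normalized log2 intensity 4.36 ± 0.08 with vehicle, SD, n = 3). With vehicle it stood at 10.98 ± 0.26 in the PR-A line and 10.30 ± 0.30 in the PR-B line, at least 72.2-fold and at least 45.0-fold above PR-null. Both clones carry PR on an expression plasmid. Whether their PGR signal and its changes come from the plasmid or from the cells' own gene was not tested. PGR fell with R5020 in both receptor lines, with a log2 fold change of -1.36 in PR-A (adjusted p = 2.17e-06) and -1.14 in PR-B (adjusted p = 2.37e-05), while the PR-null value was 0.00 (adjusted p = 1).

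**Figure D1:**
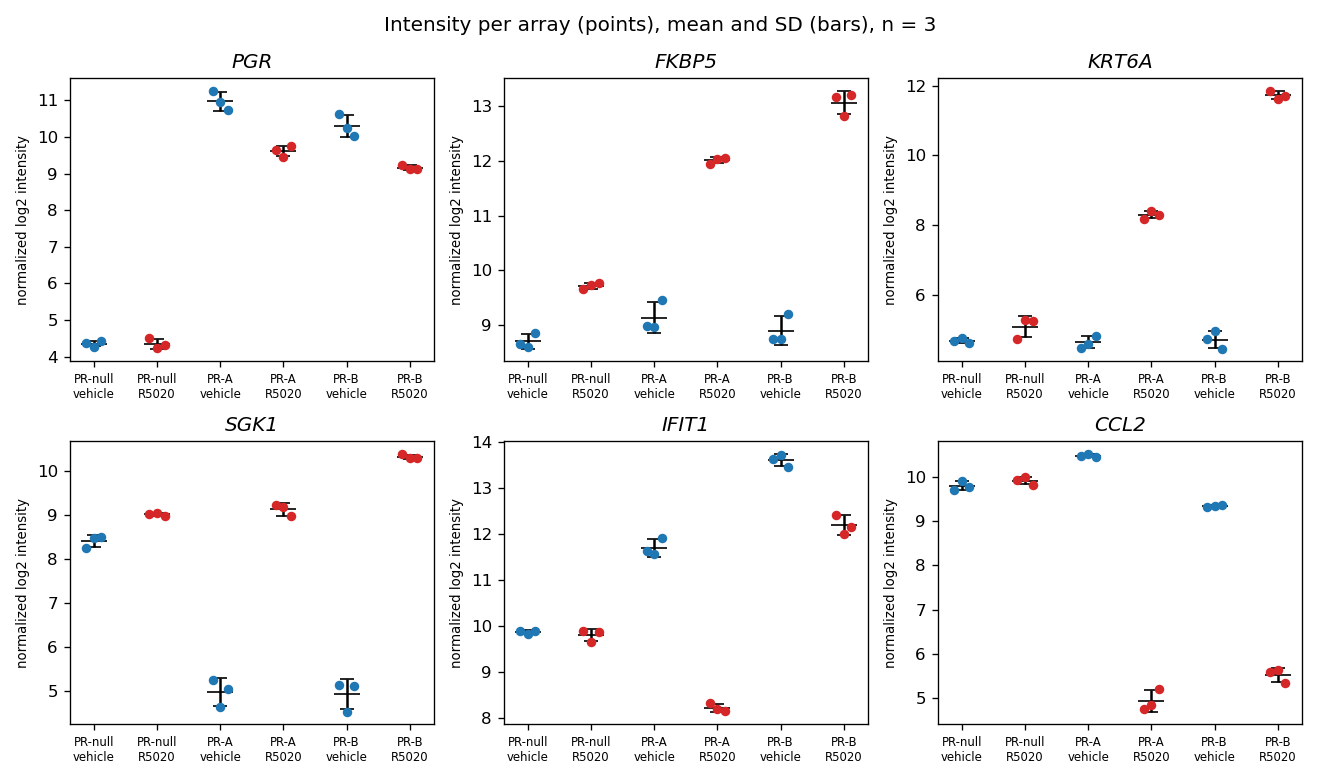
Normalized log2 intensity (vertical axis) of PGR, FKBP5, KRT6A, SGK1, IFIT1 and CCL2 on each array of the 6 groups, with bars for the mean and SD (n = 3). KRT6A reached 11.72 with R5020 in the PR-B line against 8.30 in the PR-A line, and IFIT1 stood at 13.61 with vehicle in the PR-B line against 9.87 in PR-null.

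In the PR-B line KRT6A, a keratin of stressed epidermis on chromosome 12, rose more with R5020 than any other gene named by the rule, from 4.71 ± 0.25, detected on 1 of 3 vehicle arrays, to 11.72 ± 0.12 (log2 fold change 7.01, adjusted p = 1.06e-15, n = 3). Its relative KRT6C rose at least 43.0-fold (adjusted p = 4.52e-15). SGK1, a serum- and glucocorticoid-regulated kinase on chromosome 6, rose from 4.92 ± 0.34, detected on 2 of 3 arrays, to 10.32 ± 0.05 (5.40, adjusted p = 5.77e-14). The chloride exchanger SLC26A3 rose at least 26.7-fold, the Kunitz-type protease inhibitor SPINT3 at least 29.5-fold and the phosphatase and actin regulator PHACTR3 at least 19.7-fold. ARMC12 (5.10, detected on 1 of 3 vehicle arrays), TRNP1 (4.71), the microtubule linker SYBU (4.59) and the retinol-binding protein RBP2 (4.31, detected on 1 of 3 vehicle arrays) completed the 10 largest increases. KRT6A, KRT6B and KRT6C are close relatives in sequence, and their probes may share signal, so the level of each is uncertain.

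Among the decreases in the PR-B line CCL2, a monocyte chemoattractant on chromosome 17, fell furthest of the genes named by the rule, from 9.35 ± 0.02 to 5.52 ± 0.16 (log2 fold change -3.83, adjusted p = 1.31e-13, n = 3). The decoy receptor TNFRSF11B (osteoprotegerin) fell at least 8.10-fold, to a level detected on no array. EFNB2, an ephrin ligand, and the growth factor TGFB3 changed by -2.86 and -2.82, and the interferons IFNB1 and IFNL1 by -2.75 and -2.67; IFNB1 was still detected on 2 of 3 arrays. TCL1B (-2.63), SNPH (-2.61), FGD5 (-2.59) and WFDC21P (-2.57) followed. In limma's test 3062 genes changed with R5020 in this line, 1571 up and 1491 down, and 788 of them by at least 2-fold. In all, 5181 genes had an unadjusted p under 0.05. The arrays of both groups did not overlap for 6017 genes, 31.9% against the 10% that chance gives.

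Known progestin-induced genes rose as a group in the PR-B line. Of 28 measured, 21 rose and 2 fell (22 and 2 adjusted over the list alone), with a median of 1.28 (camera adjusted p = 2.33e-21). FKBP5, a chaperone of steroid receptors, rose by 4.16, the transcription factor ZBTB16 by at least 11.97-fold and PDK4, a kinase that restrains pyruvate dehydrogenase, by at least 12.2-fold. Of 33 mitosis genes 25 rose and none fell (28 and 0 adjusted over the list alone, median 0.70, adjusted p = 9.78e-19), among them the proliferation marker MKI67 (1.45), HMMR (1.51) and NUSAP1 (1.39). DNA replication genes did not pass as a list (5 up and 1 down of 35, also 5 and 1 adjusted over the list alone, adjusted p = 0.0522), with CCNA2 at 0.90 and MCM4 at -0.95. With the replicate number as a block the adjusted p was 0.0495, and with no background correction 0.0203.

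All 32 measured interferon-stimulated genes fell in the PR-B line (32 adjusted over the list alone), with a median of -1.40 (adjusted p = 2.88e-33, or adjusted p = 0.00565 with an estimated correlation). The antiviral genes IFIT2 (-2.40), IFI44L (-2.21) and OASL (-2.04) were among them. Of 22 NF-kB and inflammatory genes 9 fell and 2 rose (9 and 2 adjusted over the list alone, adjusted p = 0.000983). The chemokine CCL5 changed by -1.91 and CCL20 by -1.38, while BIRC3, an inhibitor of apoptosis, rose by 2.42.

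Markers of epithelial type moved apart. Basal markers rose, 9 of 18 against 2 that fell (9 and 2 adjusted over the list alone, median 0.46, adjusted p = 6.71e-06), including KRT16 (3.04, from 2 of 3 arrays detected to all 3) and KRT5 (at least 4.02-fold). Luminal markers fell, 8 of 20 against 1 that rose (8 and 1 adjusted over the list alone, median -0.31, adjusted p = 0.0025), including AGR2 (-2.02) and SPDEF (-1.29). Steroid receptors and coregulators fell, 5 of 14 against 1 (5 and 2 adjusted over the list alone, adjusted p = 0.0208). FOXO target genes shifted up, 12 of 25 against 4 (12 and 6 adjusted over the list alone, median 0.22, adjusted p = 0.00429): KLF15 rose by 2.52 and the muscle ubiquitin ligase FBXO32 by 1.43, while TNFSF10, the death ligand TRAIL, changed by -1.88. Fatty acid synthesis genes rose in 7 of 19 (8 adjusted over the list alone, adjusted p = 0.000204), with THRSP at 2.13 and the fatty acid synthase FASN at 1.36. Hypoxia and glycolysis genes rose in 11 of 23 and fell in 2 (13 and 2 adjusted over the list alone, adjusted p = 6.71e-06), with NDRG1 at 2.69 and DDIT4 at 1.62. All 10 of these list calls held with an estimated correlation.

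In the PR-A line PHACTR3 rose to 9.54 ± 0.13 by a probe detected on no vehicle array (adjusted p = 8.97e-16, n = 3), and by 4.15 on the log2 scale by its other probe (adjusted p = 2.07e-14). SGK1 rose from 4.97 ± 0.31, detected on 2 of 3 arrays, to 9.12 ± 0.14. The acyl-CoA thioesterase ACOT11 rose at least 11.3-fold (0.51 on the log2 scale by its other probe) and the secreted protein SCUBE2 at least 12.3-fold. HSD11B2, the enzyme that inactivates cortisol, rose from 5.54 ± 0.20 to 9.32 ± 0.04, the tight junction protein CLDN8 from 6.09 to 10.07 and the transcriptional co-activator CITED4 from 6.56 to 10.28. TRNP1 (4.10), PDK4 (3.73) and OTULINL (3.72) were the others of the 10, the last 2 detected on 2 of 3 vehicle arrays.

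CCL2 fell further in this line than any other gene named by the rule, from 10.49 ± 0.03 to 4.93 ± 0.24, detected on 1 of 3 R5020 arrays (log2 fold change -5.56, adjusted p = 1.25e-15, n = 3). The interferon-stimulated genes IFI44L (-3.75), IFIT1 (-3.48), OAS2 (-3.22) and IFIT3 (-3.02) were also among the 10 largest decreases. Of the other 2 probes of IFIT3 1 gave -2.00 and 1 gave 0.11 (adjusted p = 0.68). TGFB3 changed by -3.22, the chemokine CCL20 by -2.92, the fractalkine receptor CX3CR1 by -2.85 (-0.57 by its other probe, adjusted p = 0.0702) and MYRFL by -3.56, and TNFRSF11B fell at least 4.72-fold. In all 4016 genes changed, 1994 up and 2022 down, 965 of them by at least 2-fold, and 5922 had an unadjusted p under 0.05. The arrays did not overlap for 6649 genes, 35.2% against 10% by chance.

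Progestin-induced genes rose in the PR-A line too, 20 of 28 against 1 that fell (21 and 1 adjusted over the list alone, median 1.30, adjusted p = 7.88e-19), with FKBP5 at 2.87 and S100P at 2.49. Again all 32 interferon-stimulated genes fell (32 adjusted over the list alone, median -1.74, adjusted p = 1.69e-34, or adjusted p = 0.00822 with an estimated correlation). DNA replication genes rose in 11 of 35 and fell in 1 (14 and 1 adjusted over the list alone, median 0.26, adjusted p = 0.000123), with POLE2 at 0.86 and GINS2 at 0.80. That list had an adjusted p = 0.0791 with an estimated correlation. Mitosis genes rose in 8 of 33 (10 adjusted over the list alone, median 0.18, adjusted p = 0.00709), MKI67 by 0.70. FOXO target genes rose in 11 of 25 and fell in 4 (12 and 4 adjusted over the list alone, adjusted p = 0.000306), with FOXO4 at 1.78 and BCL6 at 1.29. Luminal markers fell in 11 of 20 and rose in 3 (12 and 4 adjusted over the list alone, adjusted p = 0.00152), with SPDEF at -2.08 and the pioneer factor FOXA1 at -1.35. Steroid receptors and coregulators fell in 6 of 14 and rose in 1 (6 and 1 adjusted over the list alone, adjusted p = 0.00498). Basal markers did not shift as a list (6 up and 3 down of 18, 7 and 3 adjusted over the list alone, adjusted p = 0.128): KRT6A rose at least 11.1-fold and TP63 fell at least 2.55-fold. NF-kB genes fell in 7 of 22 and rose in 2 (9 and 2 adjusted over the list alone, adjusted p = 0.00716, or adjusted p = 0.069 with an estimated correlation). Hypoxia genes rose in 12 of 23 and fell in 1 (13 and 1 adjusted over the list alone, adjusted p = 5.27e-07), NDRG1 by 2.85, and fatty acid genes in 8 of 19 against 2 (8 and 2 adjusted over the list alone, adjusted p = 0.00709).

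**Figure D2:**
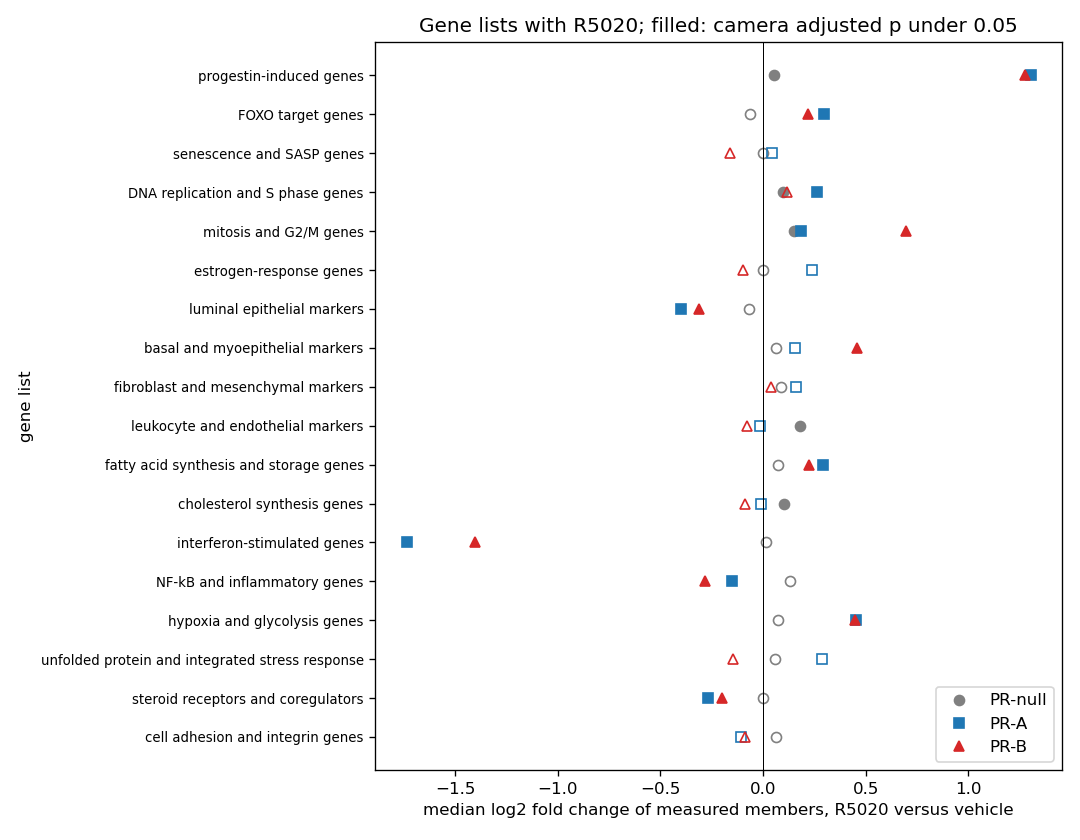
Median log2 fold change, R5020 against vehicle (horizontal axis), of each of 18 gene lists in the PR-null, PR-A and PR-B lines; filled points mark lists with an adjusted p under 0.05 in camera. Interferon-stimulated genes stood at -1.74 in PR-A, -1.40 in PR-B and 0.02 in PR-null, and progestin-induced genes at 1.30, 1.28 and 0.05.

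The PR-null line, without detected PGR, served as the control for effects of R5020 outside the receptor. A small set of genes rose in it. CLDN8 rose from 6.78 ± 0.26 to 9.03 ± 0.05 (log2 fold change 2.25, adjusted p = 9.11e-09, n = 3), the fatty acid hydroxylase CYP4F8 by 1.94 (adjusted p = 2.51e-07), HSD11B2 by 1.79 (adjusted p = 1.95e-05) and the steroid-converting enzyme AKR1C3 by 1.32 (adjusted p = 0.00021). ZBTB16 rose at least 1.71-fold (adjusted p = 0.000248), by 1 of 3 probes only, and FKBP5 by 1.02 (adjusted p = 0.00371). The chemokine scavenger ACKR3 (-1.08, still detected on 2 of 3 arrays), the potassium channel subunit KCNS3 (-1.02), CEACAM6 (-0.97), PLCE1 (-0.93) and SGSM1 (-0.88) had the largest decreases. In all 50 genes changed, 37 up and 13 down, 14 of them by at least 2-fold, and 1646 had an unadjusted p under 0.05. With no background correction the calls were 85, 54 up and 31 down, and with the authors' processed values 83, 53 up and 30 down. Non-overlapping arrays were seen for 2475 genes, 13.1% against 10% by chance.

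The size of the PR-null set and its balance of directions depended on the model and on the arrays in the fit. With a replicate block in the vehicle arrays only, 320 genes were called, 129 up and 191 down, and without the vehicle arrays numbered 3 of all lines 381, 78 up and 303 down. Both settings were chosen after seeing the data, and both kept all 50 genes. Leaving out PR-null vehicle array 3 alone gave 51 genes. A fit with the 6 PR-null arrays alone called 6 genes and lost FKBP5 (adjusted p = 0.0511) and the 5 named decreases (adjusted p = 0.0662 to 0.2), and PLCE1 was not called without R5020 array 1 (adjusted p = 0.0512). The count was 30, 33 and 33 without R5020 array 1, R5020 array 2 and vehicle array 1. Of the 37 genes that rose, 22 also rose in PR-B (3.08 expected of independent lists), 22 in PR-A (3.91 expected) and 19 in both. Progestin-induced genes shifted up in the PR-null line with 3 of 28 called (5 up and 1 down adjusted over the list alone, adjusted p = 0.0151, or adjusted p = 0.0479 with an estimated correlation), and mitosis genes with 0 of 33 called (0 adjusted over the list alone, adjusted p = 0.0123, or adjusted p = 0.0479 with an estimated correlation). Shifts of DNA replication genes (0 of 35 called, 0 adjusted over the list alone, adjusted p = 0.00381), of leukocyte and endothelial markers (0 of 8, 3 adjusted over the list alone, adjusted p = 0.0196) and of cholesterol synthesis genes (0 of 20, 0 adjusted over the list alone, adjusted p = 0.0416) were lost with an estimated correlation, with adjusted p = 0.181, 0.137 and 0.106, and that of the leukocyte list also with no background correction (adjusted p = 0.107). With the replicate number as a block the cholesterol list had an adjusted p of 0.0540. Interferon-stimulated genes did not shift (0 of 32 called, 0 adjusted over the list alone, median 0.02, adjusted p = 0.598).

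Whether the isoforms responded differently was tested as the PR-B response minus the PR-A response. Several keratins rose more in the PR-B line: the fitted difference was 4.17 log2 units for KRT6C (adjusted p = 8.41e-10), 3.35 for KRT6A (adjusted p = 3.1e-08) and 2.91 for KRT16, which was detected on 1 of 3 PR-A arrays with and without R5020. SPINT3 (3.93), the flavin monooxygenase FMO5 (3.92), the alpha tubulin TUBA3E (3.57), the signalling protein CHN2 (3.09, and 2.35 and 0.41 by its other probes, the last not called), the sulfonylurea receptor ABCC8 (3.07) and SLC26A3 (2.95) rose more with PR-B as well. KRT6C, KRT6A, SPINT3, TUBA3E, ABCC8 and SLC26A3 were detected on no vehicle array of at least 1 of these lines, so the sizes of their differences are uncertain. BATF, an AP-1 family factor, went opposite ways, from 7.52 to 6.20 in PR-A and from 6.95 to 8.82 in PR-B (difference 3.18). CITED4 rose from 6.56 ± 0.09 to 10.28 ± 0.03 in PR-A while in PR-B, at 6.84 ± 0.14 with vehicle, its log2 fold change was -0.34 (adjusted p = 0.15; difference -4.06, adjusted p = 1.6e-09, n = 3).

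CYP1B1, an estrogen-hydroxylating cytochrome P450, rose from 8.51 to 10.01 in PR-A and fell from 8.95 to 6.52 in PR-B (difference -3.93, adjusted p = 4.46e-09). SCUBE2, already at 7.85 with vehicle in PR-B and not detected with vehicle in PR-A, differed by -3.40. The metallothioneins MT2A and MT1A, metal-binding proteins whose family members are alike in sequence, rose in PR-A from 8.52 to 11.64 and from 8.25 to 10.85, and stood at 9.81 and 9.98, and at 9.16 and 9.30, in PR-B (differences -2.95 and -2.46). SEPTIN5 (-2.64), PDGFRL (-2.52), IFNB1 (-2.47), PLEKHF1 (-2.31) and FAM89A (-2.27) also had lower responses in PR-B; IFNB1 was detected on only 1 of the 6 PR-A arrays. The change of PGR itself did not differ (0.23, adjusted p = 0.68).

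In all 1232 genes differed in their response, 639 higher and 593 lower in PR-B, 494 of them by at least 2-fold, and 3349 had an unadjusted p under 0.05. With a replicate block in the vehicle arrays only, 1898 differed, 1019 higher and 879 lower. Of the genes called with R5020, 822 rose in both lines and 907 fell in both, against 166 and 159.7 expected of independent lists, and 71 changed in opposite directions. Across genes, which are not independent replicates, the fold changes of both lines had r = 0.639 and rho = 0.524, with no array in common. An effect of processing shared by both lines may add to these overlaps and correlations, which was not tested. Among the genes that moved the same way in both, 1414 had no called difference, 133 had a larger change in PR-B and 182 in PR-A. Of 2216 genes called in PR-A alone the difference was called for 489, and of 1262 called in PR-B alone for 332.

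Mitosis genes responded more in PR-B as a group: the difference was positive and called for 8 of 33 and negative for none (18 and 0 adjusted over the list alone, median 0.55, adjusted p = 8.12e-12), HMMR by 1.31 and MKI67 by 0.76. Basal markers did so for 5 of 18 (6 adjusted over the list alone, median 0.36, adjusted p = 9.95e-07), KRT6B by 1.69 and KRT5 by 1.29. Interferon-stimulated genes fell less in PR-B for 10 of 32 and more for 1 (10 and 3 adjusted over the list alone, adjusted p = 0.000792), OAS2 by 1.84. IFIT1 had 2.07 by the probe tested and -0.45 by its other probe (adjusted p = 0.341). That list call had an adjusted p = 0.356 with an estimated correlation and 0.962 with no background correction. Unfolded protein response genes were lower in PR-B for 3 of 21 (9 adjusted over the list alone, median -0.36, adjusted p = 0.000792, or adjusted p = 0.0929 with an estimated correlation), with DNAJC3 at -0.87. DNA replication genes shifted down with 1 of 35 called (1 adjusted over the list alone, adjusted p = 0.0267, or adjusted p = 0.356 with an estimated correlation). Progestin-induced genes did not shift as a list (7 higher and 6 lower of 28, 9 and 7 adjusted over the list alone, adjusted p = 0.361), with ZBTB16 at 2.56 and FKBP5 at 1.29. The ZBTB16 probe was detected on no vehicle array of these lines, so the size of its difference is uncertain.

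Set against the PR-null response, 1435 genes responded differently in PR-B (709 higher, 726 lower) and 1884 in PR-A (879 higher, 1005 lower). KRT6A rose more in PR-B by a fitted 6.60 (adjusted p = 9.91e-13), as did KRT6C, SLC26A3, SPINT3 and PHACTR3, which were detected on no PR-B vehicle array, so that the sizes of their differences are uncertain. In PR-A the excess was 3.88 for CITED4 and 3.66 for PDK4, while PHACTR3, SCUBE2 and ACOT11 also rose more but were detected by the probe tested on no PR-A vehicle array. KRT6A and PDK4 were themselves not detected on PR-null vehicle arrays. CCL2 had the lowest difference in both, -3.95 in PR-B and -5.68 in PR-A. RARRES1 (-2.91), IFIT2 (-2.87), IFNB1 (-2.75) and EFNB2 (-2.64) followed in PR-B, and IFI44L (-3.77), IFIT3 (-3.63), OAS2 (-3.46) and IFIT1 (-3.42) in PR-A. IFNB1 was detected on no PR-null array, so the size of its difference is uncertain. In PR-A against PR-null 1 other probe of IFIT3 gave -2.50 and 1 gave -0.01 (adjusted p = 0.991). Interferon-stimulated genes were lower in 29 of 32 in PR-B (32 adjusted over the list alone, adjusted p = 1.27e-36) and in 28 of 32 in PR-A (30 adjusted over the list alone, adjusted p = 8.88e-40), with adjusted p = 0.00393 and 0.00474 with an estimated correlation.

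FOXO1, the transcription factor in the title of the series, was read beside CDKN1A, the cyclin-dependent kinase inhibitor p21, and the senescence list. FOXO1 rose with R5020 in the PR-B line from 6.11 ± 0.04 to 6.67 ± 0.03 (log2 fold change 0.56, SE 0.15, adjusted p = 0.0129, n = 3). Its values were 5.75 ± 0.11 and 6.10 ± 0.24 in the PR-A line (0.35, adjusted p = 0.109) and 5.93 ± 0.27 and 6.18 ± 0.23 in PR-null (0.25, adjusted p = 0.656). The FOXO1 responses of PR-B and PR-A did not differ (0.21, adjusted p = 0.704), nor did those of PR-B and PR-null (0.31, adjusted p = 0.533). CDKN1A rose from 10.87 to 11.58 in PR-B (0.71, adjusted p = 0.00369) and from 9.78 to 10.45 in PR-A (0.67, adjusted p = 0.00472), and in PR-null its value was 0.30 (adjusted p = 0.615), with no difference called between PR-B and PR-null (0.41, adjusted p = 0.396). Senescence and secretory genes did not shift in PR-B (4 up and 3 down of 17, 4 and 5 adjusted over the list alone, adjusted p = 0.183) or in PR-A (2 and 3 of 17, 2 and 3 adjusted over the list alone, adjusted p = 0.535), and the responses did not differ as a list (adjusted p = 0.921). Within it IGFBP5, a secreted regulator of insulin-like growth factors, changed by -2.12 and the urokinase PLAU by -1.91 in PR-B.

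With vehicle the PR-B line differed from PR-null most in FABP7, a brain-type fatty acid binding protein on chromosome 6, which stood at 13.37 ± 0.05 and was detected on no array of the other lines (at least 380.1-fold, adjusted p = 7.84e-20, n = 3). Interferon-stimulated genes were higher, all 32 of 32 (32 adjusted over the list alone, median 3.17, adjusted p = 1.52e-57, or adjusted p = 0.003 with an estimated correlation): IFI44L by 5.33, IFIT3 by 5.00, IFI44 by 4.99 and IFIT2 by 4.53. The protease inhibitor CST6 (4.61, detected on 2 of 3 PR-null arrays), PSORS1C2 (4.53), the sphingosine receptor S1PR3 (4.49) and albumin, ALB (4.48), were also higher. PCP4 (-4.73), butyrylcholinesterase BCHE (-4.46), SUSD2 (-4.41), UPK3B (-3.93), the trefoil factor TFF3 (-3.69), OLFM1 (-3.50) and SGK1 (-3.49) were lower, and the defensin DEFB4A at least 12.2-fold. Basal markers were lower in 8 of 18 and higher in 1 (10 and 1 adjusted over the list alone, adjusted p = 0.000146), with CDH3 at -2.41. In all 4143 genes differed, 1976 higher and 2167 lower, 879 of them by at least 2-fold. Non-overlapping arrays were seen for 6074 genes, 32.2% against 10% by chance.

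The PR-A line differed from PR-null in 4140 genes, 2148 higher and 1992 lower, 809 of them by at least 2-fold, with non-overlapping arrays for 6131 (32.5% against 10%). IGFBP5 stood at 12.45 ± 0.21 in PR-null and 6.02 ± 0.32 in PR-A (log2 fold change -6.43, adjusted p = 4.41e-13, n = 3), the breast differentiation antigen ANKRD30A was at least 58.7-fold lower and BCHE at least 64.4-fold lower. The stem cell factor SOX2 (-3.96), SPRR3 (-4.40) and the scavenger receptor CD36 (-3.80) were lower. PSORS1C2 (4.94), KRT222 (3.80), PAGE4 (3.60), the zinc-binding glycoprotein AZGP1 (3.59) and KCNK2 (3.16) were higher. Interferon-stimulated genes were higher in 28 of 32 (29 adjusted over the list alone, median 1.29, adjusted p = 1.68e-22, or adjusted p = 0.0362 with an estimated correlation), IFI44 by 3.36. NF-kB genes were lower in 13 of 22 and higher in 3 (15 and 3 adjusted over the list alone, median -0.64, adjusted p = 3.1e-06), with the lymphotoxin LTB at least 9.18-fold lower. Basal markers were lower in 7 of 18 (9 lower and 1 higher adjusted over the list alone, adjusted p = 7.96e-05), and DNA replication genes higher in 12 of 35 (15 adjusted over the list alone, adjusted p = 7.96e-05, or adjusted p = 0.136 with an estimated correlation). With only the 6 arrays of the contrast 2750 genes were called.

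Both vehicle comparisons use the same 3 PR-null arrays. They shared 1194 higher and 1280 lower genes, against 224.9 and 228.7 expected of independent lists and 0 in simulations of unchanged groups. Simulated contrasts with no array in common also shared 0, so this 0 says nothing about the shared controls. Across genes the fold changes of both vehicle comparisons had r = 0.735 where simulations gave 0.498. Their covariance was 0.189 where simulations gave 0.0175, a difference of 0.172. The 3 PR-null arrays cannot be split so that each part keeps 2, so part of the excess may come from the shared controls.

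Compared directly with vehicle, the PR-B line exceeded the PR-A line in FABP7 (at least 374-fold, adjusted p = 5.94e-20), ANKRD30A (at least 61.1-fold) and the mesenchymal transcription factor TWIST1 (at least 15.0-fold). TM4SF1 was higher by 4.31, IGFBP5 by 4.16, ALB by 4.04 and IFNL1 by 3.31. The glycosyltransferase UGT3A2 was at least 6.56-fold lower in PR-B, NDST4 at least 5.34-fold lower and the leukotriene receptor CYSLTR1 was lower (-2.51). PGR was lower in PR-B (-0.68, adjusted p = 0.00596), a difference not called with only the 6 arrays of the contrast (adjusted p = 0.0819). In all 2018 genes differed, 919 higher and 1099 lower in PR-B; of the 351 that differed by at least 2-fold, 270 were higher and 81 lower. Non-overlapping arrays were seen for 4485 genes (23.8% against 10%), and with only the 6 arrays of the contrast 1080 genes were called.

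All 32 interferon-stimulated genes were higher in PR-B than in PR-A with vehicle (32 adjusted over the list alone, median 1.87, adjusted p = 6.85e-62, or adjusted p = 0.000949 with an estimated correlation), IFIT2 by 3.14 and HERC5 by 2.92. NF-kB genes were higher in 12 of 22 and lower in 1 (13 and 2 adjusted over the list alone, median 0.58, adjusted p = 6.37e-10), the chemokines CXCL10 by 2.87 and CCL5 by 2.13, both also known as interferon targets. FOXO target genes were higher in 9 of 25 and lower in none (10 and 0 adjusted over the list alone, adjusted p = 4.43e-06), TNFSF10 by 1.98, CDKN1A by 1.09 and the mitochondrial superoxide dismutase SOD2 by 1.00. Senescence genes were higher in 6 of 17 and lower in 1 (6 and 1 adjusted over the list alone, adjusted p = 0.000347, or adjusted p = 0.0196 with an estimated correlation), with CDKN2B at 1.12 (0.32 by its other probe, not called) and CCL2 at -1.14. Mitosis genes were lower in 5 of 33 (7 adjusted over the list alone, adjusted p = 0.0286, or adjusted p = 0.0472 with an estimated correlation), with NUSAP1 at -0.59. DNA replication genes were lower in 5 of 35 (5 adjusted over the list alone, adjusted p = 0.0106) and hypoxia genes higher in 5 of 23 (7 adjusted over the list alone, adjusted p = 0.00345), with adjusted p = 0.255 and 0.164 with an estimated correlation. Fibroblast markers shifted up through TWIST1, the only 1 of 6 called (1 adjusted over the list alone, adjusted p = 0.0472), with adjusted p = 0.197 with an estimated correlation and 0.0569 with the replicate number as a block.

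**Figure D3:**
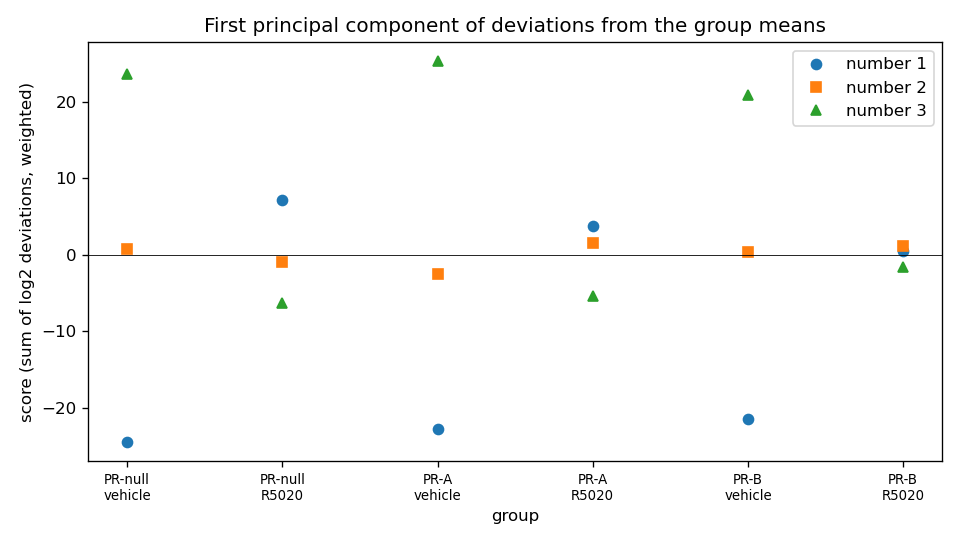
Score on the first principal component of the deviations from the group means (vertical axis, 28.1% of that variance) for each of the 18 arrays by replicate number and group. Vehicle arrays 1 of all 3 lines lie between -24.4 and -21.4 and vehicle arrays 3 between 20.9 and 25.3, while R5020 arrays lie between -6.23 and 7.20.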

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

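Of the tests below, those of probe base composition, of the correlation between the PR-null response and the vehicle deviation, of the share of the called genes' changes and of the splits of the arrays were chosen before their result was seen, and the others only after it.

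The responses of the 3 lines to R5020 differed by the test of the difference itself. Between PR-B and PR-A 1232 genes differed. The sizes given for single genes here are fitted values, which are uncertain where a gene was detected on no array of a group (among others, in PR-B with vehicle KRT6C, SLC26A3, SPINT3, TUBA3E, ABCC8 and PHACTR3, in PR-A with vehicle KRT6A, SCUBE2 and ACOT11 besides). The lists that differed were mitosis (adjusted p = 8.12e-12), basal markers (9.95e-07), interferon-stimulated genes (0.000792, or adjusted p = 0.356 with an estimated correlation and 0.962 with no background correction), unfolded protein response (0.000792, or adjusted p = 0.0929 with an estimated correlation) and DNA replication (0.0267, or adjusted p = 0.356 with an estimated correlation). The genes were KRT6C (4.17), SPINT3 (3.93), FMO5 (3.92), TUBA3E (3.57), KRT6A (3.35), BATF (3.18), CHN2 (3.09), ABCC8 (3.07), SLC26A3 (2.95) and KRT16 (2.91) upward, and CITED4 (-4.06), CYP1B1 (-3.93), SCUBE2 (-3.40), MT2A (-2.95), SEPTIN5 (-2.64), PDGFRL (-2.52), IFNB1 (-2.47), MT1A (-2.46), PLEKHF1 (-2.31) and FAM89A (-2.27) downward.

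Between PR-B and PR-null 1435 genes responded differently, with KRT6A at 6.60, KRT6C at 5.47, SLC26A3 at 5.18, SPINT3 at 5.13, PHACTR3 at 4.85, CCL2 at -3.95, RARRES1 at -2.91, IFIT2 at -2.87, IFNB1 at -2.75 and EFNB2 at -2.64. The lists that differed were progestin-induced genes (adjusted p = 5.91e-24), FOXO targets (8.45e-05), mitosis (1.63e-15), luminal markers (0.0174), basal markers (5.38e-07), leukocyte and endothelial markers (0.00913, or adjusted p = 0.0703 with an estimated correlation), fatty acid synthesis (0.000972), interferon-stimulated genes (1.27e-36), NF-kB genes (0.000211) and hypoxia genes (1.03e-06).

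Between PR-A and PR-null 1884 genes responded differently, with PHACTR3 at 5.22, SCUBE2 at 3.89, CITED4 at 3.88, ACOT11 at 3.81, PDK4 at 3.66, CCL2 at -5.68, IFI44L at -3.77, IFIT3 at -3.63, OAS2 at -3.46 and IFIT1 at -3.42. The lists were progestin-induced genes (adjusted p = 4.18e-20), FOXO targets (1.7e-06), DNA replication (0.029, or adjusted p = 0.302 with an estimated correlation), luminal markers (0.00581), fatty acid synthesis (0.0283), interferon-stimulated genes (8.88e-40), NF-kB genes (0.0016), hypoxia genes (1.79e-07) and steroid receptors (0.0174).

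For each of these 3 differences, 1 of 100 drawn splits of the arrays, the real one, gave as many genes. The other splits reached at most 1 gene for PR-B against PR-A, 1 for PR-B against PR-null and 2 for PR-A against PR-null. Those splits mix arrays of lines with different responses, which widens the spread of the genes concerned, so few calls follow from the design. Replicates may be technical and each isoform has 1 clone, so the splits do not reach chance between cultures or clones either. They cannot exclude chance for the counts of 1232, 1435 and 1884. The 3 arrays against 3 of each other comparison make 10 splits, too few for a share under 0.05: the real counts were 3062 (PR-B), 4016 (PR-A) and 50 (PR-null) with R5020, and 4143, 4140 and 2018 between lines with vehicle, and the highest of the other splits was 0 in each. The 4 vehicle splits that part every pair of same-numbered arrays include the real one, and the highest of the others was 0 as well.

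Vehicle arrays with the same number deviated from their group means together in all 3 lines, with correlations of 0.182 to 0.561. Probe base composition was associated with this deviation. Across genes the GC percent of the probe had a Spearman correlation of -0.333 with the mean of vehicle 1 minus vehicle 3, past the bound of 0.3 set for the mean. The lines taken singly gave -0.278 (PR-null), -0.316 (PR-A) and -0.252 (PR-B). No correction for GC was made, so whether base composition is a source of the deviation was not tested. A partial hormone effect in some vehicle arrays is argued against as the source of the whole pattern: vehicle arrays 1 and 3 lay as far apart on the first component in PR-null (48.1) as in PR-A (48.0) and PR-B (42.3), a ratio to the receptor lines' mean of 1.06, although R5020 moved the genes that changed in both receptor lines by only 0.120 as much in PR-null. A shared day of culture, labelling or hybridisation could give the same pattern, and the files give no slide or date to test it. The deposited columns run, line by line, through vehicle 1 and 2, then vehicle 3 and R5020 1, then R5020 2 and 3. On the first principal component with group means kept, PR-null vehicle arrays 1 to 3 stood at -48.2, -43.0 and -39.0. The PR-null R5020 arrays stood between -37.9 and -34.7. If that order follows processing, R5020 contrasts of all lines may share an effect of it, which was not tested.

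Interferon-stimulated genes were higher with vehicle in both receptor lines than in PR-null and fell with R5020. Against any 1 vehicle number the list's median kept at least 0.880 of its size. Its median fall with R5020 was 1.54 to 1.80 in PR-A and 1.23 to 1.43 in PR-B. Differences between vehicle numbers therefore do not account for the fall. The line differences were taken between same-numbered arrays, where a shared deviation cancels, so they cannot test it. Interferon genes expressed by the cells themselves are a candidate source: 2 of 7 tested, IFNL1 (at least 1.44-fold in PR-A and 14.3-fold in PR-B over PR-null, then at least 1.33-fold lower in PR-A and a log2 change of -2.67 in PR-B with R5020) and IFNL2 (at least 1.26-fold and 6.47-fold, then at least 1.16-fold lower and -1.92), went that way in both lines, although the IFNL2 changes in PR-A were not called without PR-A vehicle array 1 (adjusted p = 0.0703 with R5020 and 0.067 over PR-null) and the first not without PR-A R5020 array 3 (0.057). Leukocytes or endothelial cells cannot be told apart by the bounds set, with 3 of 17 markers detected on all PR-B vehicle arrays and called higher (among them VWF at 1.07 and CD34 at 0.80), while PTPRC, CD3D, CD3E and LYZ were detected on 0 of them. With 1 clone per isoform, a property of the clones and an effect of the receptor cannot be told apart.

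In the PR-null line 50 genes changed with R5020 although PGR was detected on none of its arrays. The PR-null fold changes followed the vehicle 3 minus vehicle 1 difference of the other lines across all genes (rho = 0.362), so the vehicle deviation may shape the background of this contrast. Scaled by its slope over all genes, the deviation accounted for a median share of 0.0195 of the called genes' changes. A large deviation widens the spread of a gene and works against its call, so a small share among called genes cannot set the deviation aside. Carry-over of receptor-line cells or RNA is argued against by PGR, which allows a share of 0.716%, while the genes called up would need a median of 23.6% and at least 3.68% over 23 genes. A response by a receptor other than PR stays open as a hypothesis, with the glucocorticoid receptor NR3C1 detected on 2 of 6 PR-null arrays.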

How the results depend on the processing

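The replicate block in the vehicle arrays only, and leaving out the vehicle arrays numbered 1 or 3 of all lines, were chosen after seeing the data. No gene called both in the main fit and under an alternative changed direction. For the test of every probe this was not counted. Genes that lost their call were checked for a change of sign only where named. Of 13285 values of 667 named gene and contrast pairs 12761 stayed on their side of the threshold, 519 lost their call, 5 gained one and 0 reversed. Most of these pairs were named because they were called in these same data, so keeping the call is partly built in. They do not stand for all called genes, and the stricter thresholds are not in this tally.

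The PR-null response was the least stable count: against 50 genes it was 85 with no background correction, 83 with the authors' processed values (63.5% and 63.9% of calls up, against 74%), 6 with only the arrays of the contrast, 27 at an adjusted p under 0.01, 320 with a replicate block in the vehicle arrays only (129 up and 191 down) and 381 without the vehicle arrays numbered 3 (78 up and 303 down). Of the 50 genes, 40, 40, 6, 50 and 50 were kept under these settings other than the stricter threshold, in that order. The cause was not tested. The vehicle-only block also gave 1898 genes for PR-B against PR-A responses. With only the arrays of the contrast, which leaves fewer residual degrees of freedom, 2750 genes differed between PR-A and PR-null and 1080 between PR-B and PR-A with vehicle.

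An adjusted p under 0.01 left, by construction, 1976 genes (PR-B with R5020), 2649 (PR-A), 632 (PR-B against PR-A), 884 (PR-B against PR-null), 1144 (PR-A against PR-null), and with vehicle 2664 (PR-A against PR-null) and 1181 (PR-B against PR-A), and overlaps of 1124 with R5020 (1729 before) and 1561 with vehicle (2474 before). A 1.5-fold threshold left 2025 (PR-B), 2556 (PR-A), and with vehicle 2556 (PR-B against PR-null), 2504 (PR-A against PR-null) and 1222 (PR-B against PR-A), and overlaps of 1081 and 1428. With an estimated correlation the shifted lists were 2 (PR-null with R5020), 2 (PR-B against PR-A), 3 and 3 (PR-B and PR-A against PR-null with vehicle) and 5 (PR-B against PR-A with vehicle).

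A replicate block over all 18 arrays gave 3215 (PR-B), 4195 (PR-A) and 50 (PR-null) genes with R5020. It gave 1315, 1502 and 1943 for the 3 differences, and 4272, 4303 and 2128 with vehicle. This block gives R5020 arrays the same number effect as vehicle arrays, although the 2 were not paired, so its counts do not test the pairing found. The block in the vehicle arrays only, with the counts given above, follows that pairing. Between lines with vehicle it kept 4137 of 4143 genes (PR-B against PR-null), 4138 of 4140 (PR-A against PR-null) and 2017 of 2018 (PR-B against PR-A). With R5020 it kept 3062 of 3062 in PR-B and 4010 of 4016 in PR-A. Genes it newly called in these comparisons are not given here. Beyond the list calls given with the results, the block over all arrays ended 5 calls of named genes. These were COL1A1 in PR-A, BHLHE40 in PR-null and in PR-A against PR-null, and HSPA5 in PR-B against PR-A. The last was ESR1 in PR-B against PR-null with vehicle. Among named genes and lists the block over all arrays changed no other call. The alternative with slide as a block was not run, since the files give no slide.

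Leaving out each array in turn gave 2425 to 2990 genes for PR-B with R5020, 3218 to 4140 for PR-A, 30 to 51 for PR-null, 1005 to 1152, 1223 to 1346 and 1607 to 1804 for the differences (PR-B against PR-A, PR-B against PR-null, PR-A against PR-null), and with vehicle 3451 to 3780 (PR-B against PR-null), 3364 to 3943 (PR-A against PR-null) and 1548 to 1760 (PR-B against PR-A); an arm left with 2 arrays shares the spread of all groups. Beyond those given with the results, list calls were lost for leukocyte markers in the PR-B response against PR-null with no background correction (adjusted p = 0.0506) and in PR-null with the authors' processed values (0.107) and with no filter (0.134). They were also lost for interferon-stimulated genes in the PR-B response against PR-A with the authors' processed values (0.918), for fibroblast markers in PR-B against PR-A with vehicle with no filter (0.13) and with median scaling (0.0514), and with median scaling for cholesterol genes in PR-null (0.0973) and luminal markers in the PR-B response against PR-null (0.0993). Calls were gained with median scaling and with no filter by FOXO target genes (0.0486 and 0.0202) and DNA replication genes (0.0446 and 0.0152) in PR-B against PR-null with vehicle and by unfolded protein response genes in PR-A against PR-null with vehicle (0.0453 and 0.0145). Luminal markers in PR-null gained one with median scaling (0.0292). With no filter unfolded protein response genes in PR-A with R5020 (0.0308) and, in the PR-B response against PR-null, the same list (0.0493) and steroid receptors and coregulators (0.042) gained one. The cause was not tested. DNA replication genes in PR-B passed under 5 settings, with adjusted p from 0.00893 (no filter) to 0.0495. Scaling to a common median turned the balance of directions, by under 10 percentage points, to 1878 higher and 2138 lower for PR-A against PR-null with vehicle, 2194 up and 1651 down for PR-A with R5020, and 715 and 565, and 891 and 811, for the responses of PR-B and PR-A against PR-null. No scaling moved the median of all genes by more than 0.0953 from its value in any contrast. Signal over background limits genes detected on no array of a group, for which folds are bounds. The difference of IFI44L between the PR-B and PR-A responses was 1.54. It was 0.11 with no background correction (adjusted p = 0.799) and 0.22 with the authors' processed values (adjusted p = 0.501). The gene was detected on all arrays. In PR-A with R5020, however, it stood at 5.20, just above those arrays' lowest detected signals of 4.91 to 4.93. The cause was not tested, and under the other settings the adjusted p was at most 0.00112.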

Other observations

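The test of a receptor acting without hormone, below, was chosen only after correlations of that kind had been seen.

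Further lists moved between the lines with vehicle. Hypoxia and glycolysis genes were higher in PR-B than in PR-null in 12 of 23 and lower in 1 (13 and 1 adjusted over the list alone, median 0.61, adjusted p = 5.93e-07), with hexokinase HK2 at 2.02 and LDHA at 1.08. In PR-A they were higher in 7 and lower in 3 (10 and 3 adjusted over the list alone, adjusted p = 0.0261, or adjusted p = 0.268 with an estimated correlation), with ANKRD37 at 2.06. Unfolded protein response genes were higher in PR-B than in PR-null in 9 of 21 and lower in 1 (10 and 1 adjusted over the list alone, adjusted p = 0.00061, or adjusted p = 0.0558 with an estimated correlation), the chaperone DNAJC3 by 1.13, while the asparagine synthetase ASNS stood at -1.42. Cell adhesion genes were lower in PR-B in 8 of 21 and higher in 2 (11 and 3 adjusted over the list alone, adjusted p = 0.00367, or adjusted p = 0.0536 with an estimated correlation), with the laminin LAMB1 at -1.80. In PR-A they were lower in 10 and higher in 4 (10 and 4 adjusted over the list alone, adjusted p = 0.0138, or adjusted p = 0.104 with an estimated correlation).

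With R5020 some lists held members that moved both ways. Estrogen-response genes in PR-B rose in 4 of 23 and fell in 6 (5 and 8 adjusted over the list alone, adjusted p = 0.372), with the carbonic anhydrase CA12 at 1.83 and RERG at -1.21. Cell adhesion genes rose in 4 of 21 and fell in 5 (4 and 5 adjusted over the list alone, adjusted p = 0.762), and unfolded protein response genes rose in 3 of 21 and fell in 5 (3 and 5 adjusted over the list alone, adjusted p = 0.144). Cholesterol synthesis genes rose in 3 of 20 and fell in 1 (4 and 2 adjusted over the list alone, adjusted p = 0.967), with a median of -0.09 where the test pointed up. Fibroblast markers (2 up and 1 down of 6, 2 and 1 adjusted over the list alone, adjusted p = 0.388) and leukocyte and endothelial markers (0 up and 2 down of 8, 1 and 3 adjusted over the list alone, adjusted p = 0.119) did not shift in PR-B.

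One hypothesis was that the receptor without hormone acts opposite to the receptor with R5020, as the interferon-stimulated genes would have it. It predicts a negative relation across genes between the R5020 response of one receptor line and the vehicle difference of the other from PR-null, 2 contrasts that share no arrays. The Spearman correlations were 0.0161 (R5020 in PR-A with vehicle in PR-B) and 0.0326 (R5020 in PR-B with vehicle in PR-A), over all 18875 genes, which are not independent replicates. Pearson's r was -0.107 and -0.0308. Of the genes called in both contrasts 894 of 1606 (55.7%) and 709 of 1304 (54.4%) moved in opposite directions. The largest class was down with R5020 and up with vehicle, 532 genes against 211.7 expected of independent lists and 396 against 169.7, although every class exceeded its expectation. The rank correlation does not show the predicted relation and the called genes lean towards it, so the hypothesis stays open.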
